A study of Homo sapiens with 12 samples.

How the data were processed

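The values used were gene counts per library, deposited by the authors as 1 table per line with 59050 gene symbols and 6 libraries each. Per the labels' protocols, cells were cultured for 48 h and libraries were made from 1 µg of RNA with a stranded poly-A kit. Per the submitters' processing notes, reads were converted with bcl2fastq 2.20.0.422 and the genome build was GRCm38.p6, a mouse build, although the tables carry human gene symbols. The aligner, the counting program and its strand setting were not given in the sources used here. All 37 rows of mitochondrially encoded genes held 0 counts in every library, so that list could not be measured.

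Counts were analysed in R 4.3.3. Symbols were matched to GENCODE 29 (GRCh38), where 56159 symbols (95.1%) were found once and carried 99.1% of the counts; coordinates are from that annotation. In each line genes were kept by edgeR's filterByExpr with its minimum count of 10. Libraries were scaled with TMM, and knockout was compared with wild type by the quasi-likelihood test of edgeR 4.0.16. The Benjamini-Hochberg adjusted p had to be under 0.05, and such genes are called higher, lower, risen or fallen. The difference of the knockout effect between lines (H1299 minus A549) and the average of both effects came from 1 fit over all 12 libraries. Fold changes are on the log2 scale, knockout over wild type, and levels are mean CPM ± SD over 3 libraries. With 3 against 3 libraries an exact permutation test has 10 splits and cannot go below p = 0.1, two-sided, so p-values rest on the model. A gene is called separated when every knockout library lies on 1 side of every wild-type library, which 10% of genes would do by chance.

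Fixed lists of genes, 31 lists with 714 genes, were written before the data were examined. Of these genes 710 were found, 22 of them by an older symbol, and OAS1, KIF23, RPL6 and H2BC5 were not analysed here. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between members, again with the correlation estimated from the data, and with fry. The rule for named genes was also written before the data were examined. It took the 12 highest and 12 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 that separated the groups, passing over clone-based, LOC and LINC names, and the 4 members of each list with the smallest adjusted p. It also took the 10 genes called in both lines in the same direction with the largest smaller change of the pair, with a mean log2 CPM of at least 1 in each line and the same rule on names, and, among genes separated in both lines, 6 genes each way for the difference and for the average. Which uncalled list members are given with their adjusted p, and which genes are named as moving in opposite directions, was chosen after their values were seen.

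For chromosome arms, a step added after the data were examined, each library's log2 CPM was expressed as its deviation from the gene's mean over the line, less the library's own median, and the median was taken over expressed genes on each arm with at least 30 of them. The 41 arm medians were compared between genotypes with limma, and an arm is called shifted at an adjusted p under 0.05, a shift of at least 0.15 and separated libraries. For centring within arms, each library's arm median was removed before the fit. The correction for GC content and length fitted a loess curve with span 0.3 per library on the values of the longest GENCODE 29 transcript, known for 97.9% of genes tested in A549 and 97.7% in H1299. Where a group had 0 counts, the fold is a lower bound from a floor of 3 counts over the group, and where it had 1 to 3 counts a 95% counting interval is given. Bounds and intervals cover counting error only. Reads from overlapping genes or close paralogs (AKR1C, HSPA1A, histone, cancer-testis and ribosomal protein genes) may be assigned to the wrong member.

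The alternatives tried were RLE size factors, no TMM scaling, a filter at 1 CPM in 3 libraries, no filter, DESeq2 1.42.0, limma-voom, the 12-library fit, an adjusted p under 0.01, a 2-fold threshold and each library left out in turn. Added after the data were examined were centring within arms, removal of chromosome 2 or of shifted arms, thinning to 1 depth and the loess correction. The scripts were tested on simulated data with known changes drawn from the real means and library sizes. In A549, over 20093 genes, 4.5%, 43.3% and 78.8% of genes changed 1.5-, 2- and 4-fold were recovered and 7.7% of calls were false. In H1299, over 20194 genes, recovery was 31.3%, 67.2% and 97% and 10.3% of calls were false. For the difference, over 22635 genes, recovery was 0%, 16.4% and 53% and 4.2% of calls were false. A planted list was found in both lines with none of 28 (A549) and 27 (H1299) other lists called. Genes were drawn independently of each other, so this does not show the error rate for real lists with correlated members. A planted arm shift of 0.3 was found as 0.31. By p alone 2 (A549) and 4 (H1299) other arms were called, and none of them passed the size rule.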

Results

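Poly-A RNA was sequenced from A549 and NCI-H1299 (H1299) cells, human lung cancer lines, either wild type or with the gene for PA200 knocked out with CRISPR/Cas9. PA200, encoded by PSME4, is a nuclear activator that caps the 20S proteasome core and is associated with the turnover of acetylated histones. There were 12 libraries in 4 groups of 3: A549 wild type, A549 PA200 knockout, H1299 wild type and H1299 PA200 knockout. The labels do not say whether the 3 libraries of a group come from separate clones or from cultures of the same cells, so the p-values measure the spread between these libraries. Total counts per library were 16599401, 21112339 and 18475211 in A549 wild type and 30645131, 30920272 and 40983933 in A549 knockout, so every A549 knockout library was deeper than every A549 wild-type library. They were 30160789, 33671009 and 21405412 in H1299 wild type and 29525006, 23241381 and 31258258 in H1299 knockout. In A549 the first principal component held 48.9% of the variance. The wild-type libraries lay at -70.1, -40 and -4.4 on it and the knockout libraries between 33.2 and 44.4, so the A549 wild-type libraries differed from each other more than the knockout libraries did. In H1299 the first component held 49% and put the wild-type libraries between -38.3 and -25.6 and the knockout libraries between 25.3 and 40.7.

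PSME4 transcript was reduced in all 6 knockout libraries. In A549 it was at 173.3 ± 30.9 CPM (counts scaled to library size) in wild type (mean ± SD, n = 3) and at 19.9 ± 3.1 in the knockout, 11.5% of wild type, with single libraries at 137.6, 192 and 190.3 against 22.8, 20.3 and 16.5. In H1299 it was at 246.5 ± 19.9 in wild type and 53.6 ± 2.3 in the knockout, 21.7% of wild type, with single libraries at 264.8, 225.3 and 249.5 against 51.9, 56.2 and 52.6. The log2 fold change was -3.13 (SE 0.19, adjusted p = 0.00109, edgeR quasi-likelihood test) in A549 and -2.20 (SE 0.08, adjusted p = 7.35e-06) in H1299. The fall was smaller in H1299 by 0.91 on the log2 scale (SE 0.20, adjusted p = 0.0277 for the difference between lines). After centring within chromosome arms PSME4 stood at -2.66 in A549 and -2.25 in H1299, which are closer, and the difference was not tested again. PSME4 lies on the short arm of chromosome 2, from 53864067 to 53970840 on the minus strand of GRCh38. The counts cover the whole gene and do not show which part was edited.

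**Figure D1:**
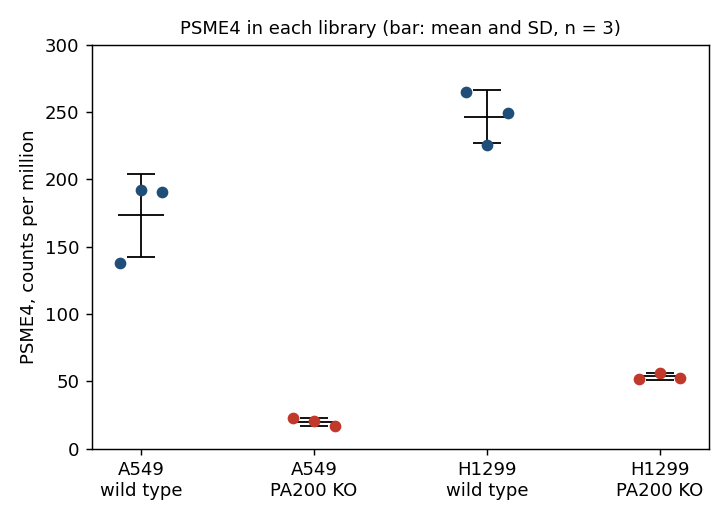
PSME4 in CPM in each of the 12 libraries, with the mean and SD of each group of 3. The A549 knockout libraries sit between 16.5 and 22.8 and the H1299 knockout libraries between 51.9 and 56.2, all below the wild-type libraries of their line.

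The comparison of knockout with wild type in A549 asked which transcripts differ when PA200 is missing from this line. Of 20093 genes tested, 199 were higher and 231 lower in the knockout, 430 in all, of which 300 changed at least 2-fold. Several of the genes that rose most were close to silent in wild type. PRICKLE1, a planar cell polarity protein, rose from 0.19 ± 0.06 to 12.9 ± 3.88 CPM (log2 fold change 5.99, SE 0.36, adjusted p = 0.00109). CPE, a carboxypeptidase that processes prohormones, OLFML3, a secreted olfactomedin-like protein, and PABPC4L, a poly(A)-binding protein, had 4, 10 and 4 counts in total over the 3 wild-type libraries and 492, 983 and 426 over the knockout libraries, with log2 fold changes of 5.84, 5.78 and 5.70. GRAMD2B (4.87) and PRR15 (4.73) were at 7 and 9 wild-type counts. Genes that rose from a measurable level included TM4SF4, a tetraspanin-like membrane protein (4.24), GASK1B (from 0.79 ± 0.45 to 12.9 ± 11.9 CPM), EHF, an epithelial ETS transcription factor (3.81), and the phosphatase PTPRE (3.66). C4BPB (4.08) and C4BPA (3.72), the chains of the complement inhibitor C4b-binding protein, rose together.

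Among the genes that fell most in A549 knockout, RSPO3, a secreted enhancer of Wnt signalling, was the most abundant in wild type: it dropped from 202 ± 48.4 to 18.2 ± 11.1 CPM (log2 fold change -3.47, SE 0.50, adjusted p = 0.0218). SLCO2B1, an organic anion uptake transporter, fell from 21.5 ± 9.74 to 0.83 ± 0.23 (-4.71), and ADAM23, an integrin-binding membrane protein, from 18.4 ± 1.47 to 0.88 ± 0.63 (-4.33). The others were PTPRN2 (-4.36), FAM78A (-3.34), RTN4RL2 (-3.05), the laminin chain LAMC3 (-3.02), the thrombin receptor F2RL2 (-3.01), the lipoprotein lipase inhibitor ANGPTL4 (-2.82), the peroxisomal oxidase ACOX2 (-2.69) and HHIPL2 (-2.60). All 430 called genes separated the 3 knockout from the 3 wild-type libraries. Of all tested genes 25.3% did so, against 10% by chance. The count depended on every library: it was 211 without wild-type replicate 1, 10 without wild-type replicate 2, 1016 without wild-type replicate 3, and 139, 68 and 59 without knockout replicates 1, 2 and 3, and 7 genes were called in every one of these fits. DESeq2 called 1540 genes, and 8 genes passed an adjusted p under 0.01.

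NRF2 target genes, which encode antioxidant and NADPH-producing enzymes and are known to be highly expressed in A549 because of a KEAP1 mutation, were lower in A549 knockout. Of 24 measured members 21 had a negative log2 fold change, with a median of -0.49. Of these, 3 fell and none rose over all genes tested, and 15 fell when adjusted over the list alone (camera adjusted p = 5.32e-07 with the preset correlation, adjusted p = 0.617 with an estimated correlation). SRXN1, which repairs oxidised peroxiredoxins, fell from 462 ± 55.7 to 272 ± 14.1 CPM (-0.76, SE 0.13, adjusted p = 0.0365). AKR1C2, an aldo-keto reductase with close paralogs, changed by -0.59 and OSGIN1 by -1.37 (both adjusted p = 0.0487). TKT, transketolase, stood at -0.71 and did not pass (adjusted p = 0.0527). Cytosolic ribosomal protein genes were lower as a group: 60 of 62 members, all but 2, had a negative log2 fold change, with a median of -0.29. None passed over all genes or when adjusted over the list alone (camera adjusted p = 3.73e-06, adjusted p = 0.947 with an estimated correlation of 0.88 between members), and the call was lost without wild-type replicate 1 (adjusted p = 0.0921). RPL31 stood at -0.93 and RPS28 at -0.90, neither past the threshold. After centring within chromosome arms they stood at -0.48 and -0.67. Across all genes with known values, the log2 fold change in A549 had a Spearman correlation of -0.25 with GC content and 0.164 with transcript length, against -0.346 and 0.047 in H1299 (genes are not independent replicates). No list was tested with these removed.

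Nuclear-encoded respiratory chain genes were also lower in A549 knockout, with 40 of 48 members below 0 and a median of -0.17. A single member, the ATP synthase subunit ATP5MC3, fell (-0.82, SE 0.11, adjusted p = 0.0179; -0.36 and adjusted p = 0.19 after centring within chromosome arms) and 4 fell when adjusted over the list alone (camera adjusted p = 0.0221, adjusted p = 0.947 with an estimated correlation). ATP5MC3 and COX5B (-0.93, adjusted p = 0.0571) both lie on chromosome 2, whose genes were lower as a whole, and the list missed the threshold after each library was centred within chromosome arms (adjusted p = 0.0617). It also missed it without wild-type replicate 1 (0.664), knockout replicate 1 (0.0888) and knockout replicate 3 (0.193). Alveolar type II and airway genes were higher: 5 of 6 measured members were above 0, with a median of 0.98. LPCAT1, which makes surfactant phosphatidylcholine, rose from 49.7 ± 3.19 to 88.9 ± 15 CPM (0.84, SE 0.14, adjusted p = 0.0383), and 4 rose when adjusted over the list alone (camera adjusted p = 0.0101, adjusted p = 0.714 with an estimated correlation, adjusted p = 0.054 without wild-type replicate 1). The mucin MUC5B stood at 2.18 (adjusted p = 0.0794) and AGR2 at 1.11 (adjusted p = 0.131). None of these 4 camera calls held with an estimated correlation, a setting that called no list in A549.

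Extracellular matrix genes contained 8 called genes in A549, 7 higher and 1 lower of 34 measured, and 12 higher and 5 lower when adjusted over the list alone, while the list as a whole missed the threshold (camera adjusted p = 0.0539, adjusted p = 0.714 with an estimated correlation). The microfibril protein FBN1 rose by 0.91, the basement membrane collagens COL4A6 and COL4A5 by 1.22 and 0.96, and the matricellular protein TNC by 3.65. After centring within arms FBN1 (0.69, adjusted p = 0.0604) and COL4A5 (0.94, adjusted p = 0.0541) missed the threshold. The epithelial list held 2 genes that rose, the keratin KRT19 (from 33.6 ± 14.7 to 149 ± 17.9 CPM, 2.15, adjusted p = 0.0247) and the desmosome protein PKP2 (1.36), of 18 measured, with CDH1 at 0.75 (adjusted p = 0.101) and JUP at -0.97 (adjusted p = 0.0793), and 4 higher and 2 lower adjusted over the list alone. Among hypoxia and glycolysis genes 2 of 20 fell, NDRG1 (-1.58) and KDM3A (-0.70), with 2 higher and 6 lower over the list alone. ULK1, a kinase that starts autophagy, fell by 0.89 on the log2 scale among 27 autophagy and lysosome genes (1 higher and 6 lower over the list alone), where SQSTM1 stood at -0.77 (adjusted p = 0.0826). In the MAPK output list of 17, the phosphatase DUSP5 fell (-1.13) and the receptor EPHA4 rose (3.61), with 1 higher and 2 lower over the list alone. None of these lists was called by camera.

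No camera call was made in A549 for any proteasome list. The 20S core list had 0 of 14 members called and a median of -0.06 (PSMB6 at -0.43, adjusted p = 0.193), the list of other activators and assembly factors 0 of 14, and the immunoproteasome and MHC class I list 0 of 18, with none in these 3 lists adjusted over the list alone. In the 19S regulator list 1 of 19 fell, PSMD14 (-0.58), over all genes and over the list alone. The 19S, respiratory chain, alveolar and airway, and autophagy and lysosome lists each had 1 called member, given above. Other lists with 1 called member, each lower, were the p53 targets (TP53I3, -0.94, 1 of 23), DNA double-strand break repair (NHEJ1, -0.76, 1 of 24) and mesenchymal genes (TWIST2, -1.16, 1 of 17). Adjusted over the list alone, the p53 and repair lists kept 1 lower and the mesenchymal list had 5 higher and 3 lower. PSMD14, TP53I3, NHEJ1, TWIST2 and KDM3A all lie on chromosome 2, and none of these 5 kept its call after centring within chromosome arms. No member was called in the lists of interferon-stimulated (24 measured), G1/S (25), G2/M (24), replication-dependent histone (12), endoplasmic reticulum stress (19), ATF4 (19), heat shock (16), cholesterol synthesis (20), TGF-beta target (17), YAP and TEAD target (17), NF-kappaB (19) or cancer-testis genes (5). Adjusted over the list alone, these had 5 higher and 2 lower interferon-stimulated genes, 1 lower G1/S gene, 2 lower heat shock genes, 1 higher and 1 lower TGF-beta target, 2 higher and 1 lower YAP and TEAD targets, and 1 higher and 3 lower NF-kappaB genes, and none in the others. MCM6 in the G1/S list stood at -0.57 (adjusted p = 0.0531) and BUB1 in the G2/M list at -0.58 (adjusted p = 0.0759), both on chromosome 2. The camera adjusted p of all these uncalled lists other than extracellular matrix ranged from 0.281 to 0.982. The histone list passed without knockout replicate 1 (adjusted p = 0.0144), and the extracellular matrix list passed without wild-type replicate 2 (0.0246), without knockout replicate 3 (0.0149) and after centring within arms (0.0395). Markers of leukocytes (3 measured) and of fibroblasts and endothelium (2 measured) were too few to test, had medians of -0.20 and -0.77, and held no called member over all genes, with 1 lower fibroblast and endothelial marker over that list alone.

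In A549 the knockout libraries were lower over the whole of chromosome 2, the chromosome that carries PSME4. Of its expressed genes 91.2% had a log2 fold change below 0, with a median of -0.47, and it held 118 of the 231 genes that fell (51.1%) but 6.4% of the genes tested. The shift between the group means was -0.468 (SE 0.0929) on the short arm and -0.462 (SE 0.046) on the long arm, and on both arms every knockout library lay below every wild-type library. On the short arm the deviations of knockout replicates 1, 2 and 3 were -0.104, -0.151 and -0.451, so replicate 3 stood apart. On the long arm they were -0.209, -0.270 and -0.230. In limma over 41 chromosome arms the long arm passed the threshold (adjusted p = 0.00279) and the short arm missed it (adjusted p = 0.0525). Without the genes of chromosome 2 the count in A549 was 153, 102 higher and 51 lower. After each library was centred within each arm it was 236, 146 higher and 90 lower against 199 and 231 before, and PSME4 remained at -2.66. Of 52 named genes called in A549 besides PSME4, 20 lost their call after this step, 9 of them among the 11 on chromosome 2. CPE (5.69), GRAMD2B (4.81), C4BPA (3.70), PTPRN2 (-4.40), OSGIN1 (-1.36) and GASK1B, on other chromosomes or without an arm, lost it with little change in fold, at adjusted p from 0.0519 to 0.0619.

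**Figure D2:**
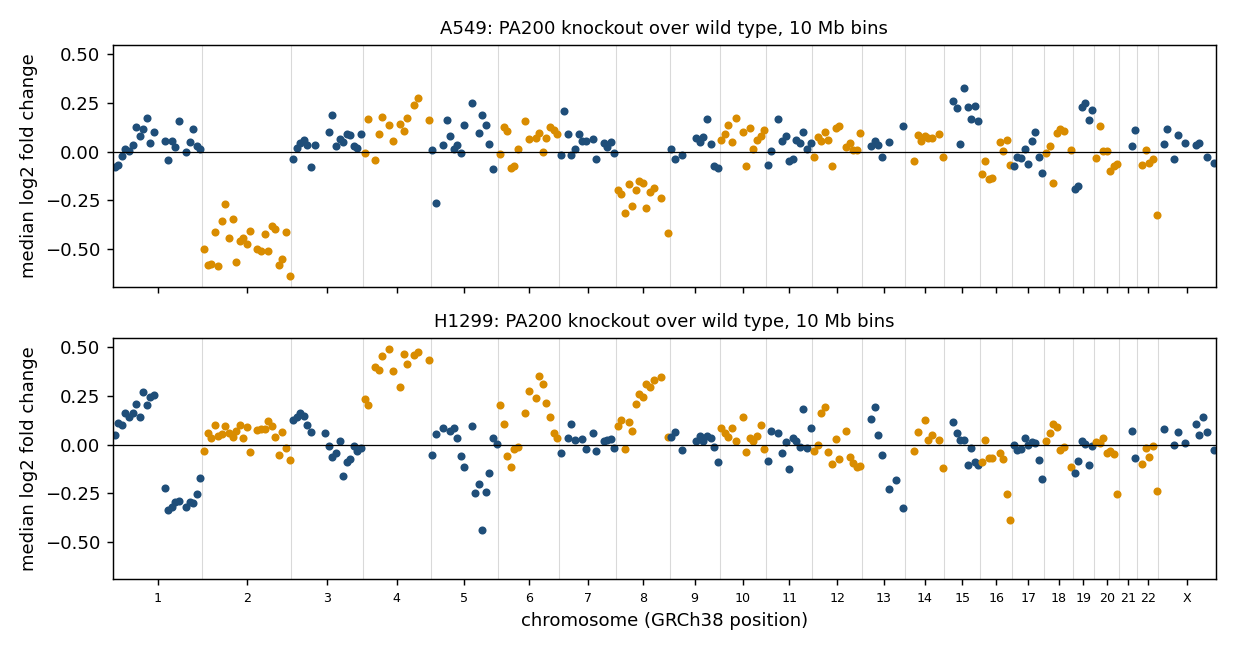
Median log2 fold change (knockout over wild type, vertical axis) of expressed genes in 10 Mb bins with at least 20 genes, along chromosomes 1 to 22 and X (horizontal axis, colours alternate by chromosome), for A549 above and H1299 below. A549 is below 0 along chromosome 2, where the long arm shift is -0.462, and H1299 is above 0 along chromosome 4 and most of the long arm of chromosome 8 and below 0 along the long arm of chromosome 1.

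The same comparison in H1299 gave 1786 called genes of 20194, 941 higher and 845 lower, of which 376 changed at least 2-fold. The balance was not stable, with 618 higher and 652 lower after centring within arms, 1132 and 1183 with DESeq2 and 1336 and 1741 with no low-count filter. PPARGC1A, the co-activator that drives mitochondrial biogenesis, had 0 counts in all 3 wild-type libraries and between 102 and 142 in the knockout libraries, at least 128-fold higher against a floor of 3 counts over the group. ADD2, a cytoskeletal adducin, rose from 0.90 ± 0.47 to 21.2 ± 1.45 CPM (log2 fold change 4.48, SE 0.25, adjusted p = 7.95e-05). FHAD1 (4.07), the growth factor GDF6 (3.57), ADAM23 (3.35), the mannosidase MAN1A1 (3.28), the sodium channel SCN9A (2.93), the meiotic cyclin CCNA1 (2.86), TMEM156 (2.86), EYA4 (2.69), the fatty acid elongase ELOVL4 (2.65) and EXPH5 (2.49) completed the 12 highest. EYA4 missed the threshold in DESeq2 (adjusted p = 0.0655). PPARGC1A and TMEM156 lie on chromosome 4 and GDF6 on the long arm of chromosome 8, arms with shifted medians, and all 3 kept their calls after centring within chromosome arms.

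Among the genes that fell most in H1299 knockout, TGFA, a ligand of the EGF receptor, dropped from 14.5 ± 2.92 to 0.21 ± 0.21 CPM (-5.99, SE 0.37, adjusted p = 0.000104), and EPAS1, the hypoxia-inducible factor HIF-2 alpha, from 16.5 ± 3.77 to 0.27 ± 0.10 (-5.90, SE 0.28, adjusted p = 3.1e-05). NPAS2, a circadian transcription factor, fell from 102 ± 14 to 4.41 ± 2.33 (-4.50), and SFRP1, a secreted Wnt antagonist, changed by -5.43 with widely spread wild-type libraries (33.8 ± 28.6). CCNJL (-5.01), the endothelial lipase LIPG (-4.90), SH3TC2 (-4.87), the matrix proteins THBS1 (-4.21), FBLN2 (-3.99) and COL13A1 (-3.89), the actin regulator EPS8 (-3.74) and FLRT2 (-3.48) also fell. Of the 1786 called genes 1785 separated the groups, as did 30.6% of all tested genes against 10% by chance. The count was 1176 and 895 without wild-type replicates 2 and 3 and 801 and 471 without knockout replicates 2 and 3, and 397 genes were called in every fit that left out a library. It was 323 at an adjusted p under 0.01.

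TGF-beta target genes were lower in H1299 knockout. Of 17 measured, 13 were below 0, the median was -0.48, and 5 fell and none rose, or 1 rose and 7 fell when adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.634 with an estimated correlation). TGFBI, a matrix protein induced by TGF-beta, fell from 148 ± 27.8 to 37.8 ± 13 CPM (-1.96, SE 0.23, adjusted p = 0.00271), and PMEPA1, a feedback inhibitor of the pathway, from 55.5 ± 7.65 to 15.9 ± 5.57 (-1.80, SE 0.22, adjusted p = 0.00292). ID3 (-0.99) and ID1 (-1.07) fell as well; both are also targets of BMP signalling. Extracellular matrix genes were lower with a median of -0.49 over 23 members, of which 7 fell and 2 rose, or 9 fell and 3 rose over the list alone (camera adjusted p = 0.0234, adjusted p = 0.634 with an estimated correlation). COL13A1 and LAMB1 (-1.74) fell and NID1 rose from 6 counts in total in wild type to 87 (3.78). NID1 lies on the shifted long arm of chromosome 1 and kept its call after centring within arms. The list missed the threshold without wild-type replicate 1 (0.0741) and without knockout replicate 2 (0.0774). In the mesenchymal list 3 of 13 fell, fibronectin FN1 (-1.70, adjusted p = 0.000319), the metalloproteinase MMP14 (-0.68) and vimentin VIM (-0.31), with 1 higher and 4 lower over the list alone, and the list itself was not called (camera adjusted p = 0.368).

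Immunoproteasome and MHC class I genes were lower in H1299 knockout: 17 of 18 members were below 0, with a median of -0.18. Of the members 10 lie on the short arm of chromosome 6, where the 10 Mb bin from 30 Mb had a median of -0.116 and knockout replicate 3 stood at -0.178 for the whole arm, against 0.061 and 0.043 in knockout replicates 1 and 2. The peptide-loading protein TAPBP (-0.43, adjusted p = 0.0247) and the immunoproteasome subunit PSMB9 (-0.52, adjusted p = 0.0285) fell, the latter at -0.47 and not called after centring within arms (adjusted p = 0.0675), and IRF1 stood at -0.40 (adjusted p = 0.0531), with 4 lower over the list alone (camera adjusted p = 0.011, adjusted p = 0.634 with an estimated correlation). G2/M genes had a median of -0.16 over 24 members, 4 lower and 1 higher, or 6 lower and 1 higher over the list alone (camera adjusted p = 0.011, adjusted p = 0.736 with an estimated correlation, adjusted p = 0.0538 without knockout replicate 2). The spindle protein ASPM (-0.50), the kinetochore protein CENPF (-0.57) and the kinase NEK2 (-0.52) lie on the long arm of chromosome 1 and cyclin CCNA2 (0.34) on chromosome 4, arms with shifted medians. Double-strand break repair genes were higher, with 18 of 24 above 0, a median of 0.12 and 3 that rose, or 4 over the list alone (camera adjusted p = 0.0242, adjusted p = 0.634 with an estimated correlation). They were XRCC2 (0.36), NBN (0.33) and PRKDC (0.27), the last 2 on the shifted long arm of chromosome 8. This list missed the threshold without wild-type replicates 1, 2 and 3 (0.052, 0.0579 and 0.0565) and without knockout replicate 2 (0.0876). Nuclear-encoded respiratory chain genes were lower, with 36 of 48 below 0, a median of -0.09 and 4 that fell, among them COX4I1 (-0.54, adjusted p = 0.0071) and SDHC (-0.43), the latter on the long arm of chromosome 1, or 7 lower and 2 higher over the list alone (camera adjusted p = 0.0401, adjusted p = 0.634 with an estimated correlation). It missed the threshold without wild-type replicate 1 (0.166), knockout replicate 1 (0.179) and knockout replicate 2 (0.0538). All 6 lists kept their camera calls after centring within arms, with adjusted p from 0.0017 to 0.0244. Centring removes the median of a whole arm and can leave shifts of parts of an arm, such as the bin on chromosome 6. None of these 6 camera calls held with an estimated correlation, a setting that called no list in H1299.

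Apart from the immunoproteasome and MHC class I list, no proteasome list was called in H1299, but the other activators and assembly factors passed after centring within arms (camera adjusted p = 0.0378, against 0.253 before). PSMB4 (-0.37) in the 20S core (14 measured, none over the list alone) and PSMD4 (-0.35) in the 19S regulator (19 measured, 1 lower over the list alone) fell, both on the long arm of chromosome 1, and DDI2, the protease that activates the proteasome gene regulator NFE2L1, rose (0.48) among 14 other activators and assembly factors (1 higher over the list alone). PSMD7 stood at -0.35 (adjusted p = 0.0735). Counts of called genes in the other lists, over all genes and then over the list alone, were 2 higher and 1 lower, then 2 and 3, of 22 interferon-stimulated genes (HERC6 0.86, IFIH1 -0.61), 2 higher and 1 lower, then 2 and 1, of 25 G1/S genes (CCNE2 0.35, CDT1 -0.50), 2 higher, then 3 higher and 2 lower, of 20 p53 targets (RRM2B 0.34, PLK2 0.98) and 3 lower in both counts of 18 ATF4 genes (SHMT2 -0.33, SLC7A5 -0.45). They were 1 lower, then none, of 16 heat shock genes (HSPA1A -0.43), 1 higher and 1 lower in both counts of 21 NRF2 targets (UGDH 0.59, OSGIN1 -0.69), 2 lower, then 1 higher and 5 lower, of 28 autophagy and lysosome genes (LAMP1 -0.39, CTSD -0.45) and 1 higher, then 2 higher and 3 lower, of 18 hypoxia and glycolysis genes (HK2 0.57).

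Cholesterol synthesis held 2 higher (MSMO1 0.63, SQLE 0.51) and 2 lower (among them MVD -0.42) of 19 members in H1299, with 5 higher and 3 lower over the list alone. Of 10 epithelial genes 2 rose (OCLN 0.54, CLDN1 0.52) and 2 fell (KRT18 -0.83, KRT8 -1.03), with 2 and 3 over the list alone. Among 14 YAP and TEAD targets CCN1 (0.41) and CCN2 (0.42) rose and PTPN14 (-0.58) fell, with 5 higher and 4 lower over the list alone. Of 12 NF-kappaB genes NFKB1 (0.48) rose and LIF (-0.76) and ICAM1 (-0.59) fell, with RELB at 0.59 (adjusted p = 0.0557) and 4 higher and 2 lower over the list alone. Of 15 MAPK output genes DUSP6 (0.44) and EGR1 (1.26) rose and EPHA2 (-0.41) fell, with 3 higher and 3 lower over the list alone. Of 62 ribosomal protein genes RPS3A (0.43), RPL34 (0.35) and RPL7 (0.22), on chromosomes 4 and 8, rose and RPL13 (-0.47) fell, with 2 higher and 1 lower over the list alone. No member was called, over all genes or over the list alone, among 12 replication-dependent histones (H1F0, in fact a replacement histone, at -0.54, adjusted p = 0.0675), 19 endoplasmic reticulum stress genes (HERPUD1 at -0.26, adjusted p = 0.07), 15 cancer-testis antigens (MAGEA10 at 0.26, adjusted p = 0.0733), or the 4 alveolar and airway, 2 leukocyte and 2 fibroblast and endothelial genes, which were too few to test and had medians of 0.06, 0.12 and -0.08. The camera adjusted p of the uncalled lists ranged from 0.108 to 0.969. The fry test, which asks whether a list moves on balance in one direction, called NRF2 targets in A549 (adjusted p = 0.0284) and cancer-testis antigens in H1299 (adjusted p = 0.0115) and no other list in either line. In A549 the median, the mean and camera's direction differed in sign for the 19S regulator, endoplasmic reticulum stress, interferon-stimulated, cancer-testis, MAPK output and mesenchymal lists, and in H1299 for the G1/S, heat shock, cholesterol synthesis and YAP and TEAD lists.

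**Figure D3:**
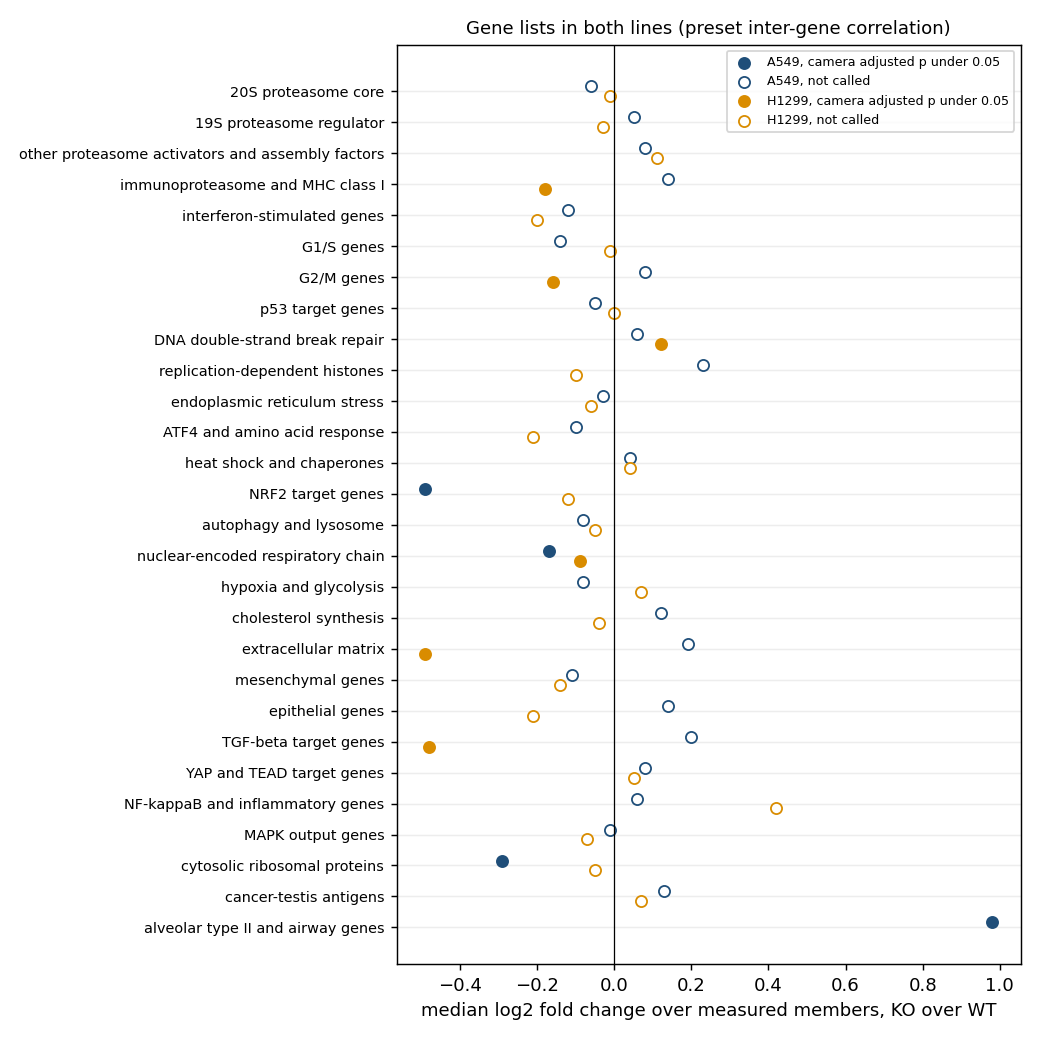
Median log2 fold change over the measured members of each tested gene list (horizontal axis, knockout over wild type), with A549 in blue and H1299 in orange. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, 4 lists in A549 and 6 in H1299, and open points did not.

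The medians of chromosome arms were also shifted in H1299 knockout. The short and long arms of chromosome 4 were higher by 0.271 (SE 0.0183, limma adjusted p = 0.000238) and 0.407 (SE 0.0412, adjusted p = 0.00128), the long arm of chromosome 8 was higher by 0.255 (SE 0.0341, adjusted p = 0.00398), and the long arm of chromosome 1 was lower by 0.296 (shift -0.296, SE 0.047, adjusted p = 0.00755). On chromosome 8 the end was not shifted: the 10 Mb bin from 140 Mb, with 85 genes, had a median of 0.037, against 0.208 to 0.406 in the bins from 50 to 130 Mb. On each of these 4 arms every knockout library lay on one side of every wild-type library. They held 556 of the 1759 called genes with a chromosome arm (31.6%) and 9.7% of such genes tested, and 534 of the 556 moved in the direction of their arm. The long arms of chromosomes 6 (shift 0.212, adjusted p = 0.16) and 16 (shift -0.152, adjusted p = 0.183) missed the threshold, with separated libraries. They held 80 higher and 61 lower calls (Fisher's exact test across genes, adjusted p = 7.87e-24 and 3.94e-16). Genes on an arm are not independent replicates, so these p-values do not measure the spread between libraries. Fisher's test also passed for lower calls on the long arms of chromosomes 5 (adjusted p = 9.82e-08) and 13 (0.0469). It passed for higher calls on the short arm of chromosome 1 (0.000258), and none of these arms was called shifted. MAN1A1, EYA4 and ELOVL4 lie on the long arm of chromosome 6 and kept their calls after centring within arms. COX4I1, RPL13, SLC7A5, MVD, CDT1 and OSGIN1 lie in the 10 Mb bin from 80 Mb on chromosome 16, whose median log2 fold change was -0.385. COX4I1 and RPL13 kept their calls after centring, at -0.39 and -0.31. Centring takes out the median of the whole arm, shifted by -0.152, and so leaves part of the larger shift of this bin. These 2 changes may still hold that part. The others did not pass, at -0.54 for OSGIN1 (adjusted p = 0.0782), -0.34 for CDT1 (adjusted p = 0.0622), -0.30 for SLC7A5 and -0.27 for MVD. On chromosome 5 the bin from 140 Mb, with SH3TC2, had a median of -0.436. Without the genes of the 4 shifted arms 928 genes were called, 432 higher and 496 lower. After centring within arms the NBN, PRKDC, ASPM, CENPF, NEK2, SDHC, PSMB4, PSMD4, RPS3A, CCNE2, RRM2B, HERC6, MSMO1, SQLE, PTPN14 and NFKB1 changes no longer passed, and CCNA2, RPL34 and RPL7 stood at -0.07, -0.06 and -0.03, while UGDH on chromosome 4 kept its call, at 0.32. The 10 Mb bins along chromosome 4 had medians from 0.202 to 0.492. Centring removes only the median of the arm, so the UGDH change may still hold part of a larger local shift. Of 95 named genes called in H1299 besides PSME4, 35 lost their call after this step, 22 of them among the 29 on the 4 shifted arms. PLK2 (1.10, adjusted p = 0.0563), SHMT2 (-0.26, 0.0635), HSPA1A (-0.39, 0.0616), HK2 (0.53, 0.0572), CLDN1 (0.58, 0.0778) and ICAM1 (-0.48, 0.0527), on other arms, were among those lost. Chromosome 2 itself was not shifted in H1299, with a median log2 fold change of 0.04.

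The 2 lines were then compared to ask whether loss of PA200 changed the same genes in both. Of 18007 genes tested in both lines 59 were called in both, 27 in the same direction and 32 in opposite directions, against 13.2 and 13.5 expected for independent lists. The genes called in the 2 lines overlapped more than independent lists (Fisher's exact test across genes, two-sided, odds ratio 2.57, p = 7.23e-09), but not in direction. Genes are not independent replicates, so this p-value does not measure the spread between libraries. Fisher's exact test of the overlap did not pass without A549 wild-type replicate 2 (p = 0.247), knockout replicate 2 (p = 0.175) or knockout replicate 3 (p = 0.222). The log2 fold changes across genes, which are not independent replicates, had a Spearman correlation of 0.07 and a Pearson correlation of 0.015. Of the genes called in H1299 53.3% had the same sign in A549. Genes that moved in opposite directions included ADAM23 (-4.33 and 3.35), TGFA (1.04 and -5.99), THBS1 (1.09 and -4.21) and LIPG (3.67 and -4.90). Genes higher in both lines included GLRB, a glycine receptor subunit (2.55 in A549 and 1.26 in H1299), ADAMTS16 (2.07 and 1.19) and the growth factor PDGFC (2.29 and 0.93). Genes lower in both included, besides PSME4, the heparan sulfate proteoglycan GPC1 (-1.26 and -1.25), the Rac exchange factor PREX1 (-1.08 and -1.75), SFRP1 (-0.99 and -5.43), TBC1D8 (-0.97 and -1.03), LRIG1, an inhibitor of receptor tyrosine kinases (-1.21 and -0.88), and NPAS2 (-0.85 and -4.50). GPC1, TBC1D8 and NPAS2 lie on chromosome 2 and lost their A549 call after centring within arms, at -0.81 (adjusted p = 0.0615), -0.51 (adjusted p = 0.0803) and -0.39 (adjusted p = 0.107). The call was also lost by GLRB (2.40, adjusted p = 0.0616), PDGFC (2.13, adjusted p = 0.0577) and SFRP1 (-0.75, adjusted p = 0.0687) from other chromosomes. GLRB and PDGFC lie on the long arm of chromosome 4, which was shifted by 0.407 in H1299 and by 0.171 in A549, where it was not called. PDGFC also lost its H1299 call after centring (0.54, adjusted p = 0.0974). Of the 15 genes lower in both lines, all but AC106760.1, LRIG1, OSGIN1, PREX1 and SFRP1 lie on chromosome 2, lower as a whole in A549. After centring within arms 9 genes were higher and 4 lower in both lines, against 12 and 15 before. Those called in opposite directions then numbered 16. The same-direction count rested on single A549 libraries: it was 14, 1 and 64 without A549 wild-type replicates 1, 2 and 3, 10, 3 and 2 without A549 knockout replicates 1, 2 and 3, 16 without H1299 wild-type replicate 3 and 17 without H1299 knockout replicate 3.

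**Figure D4:**
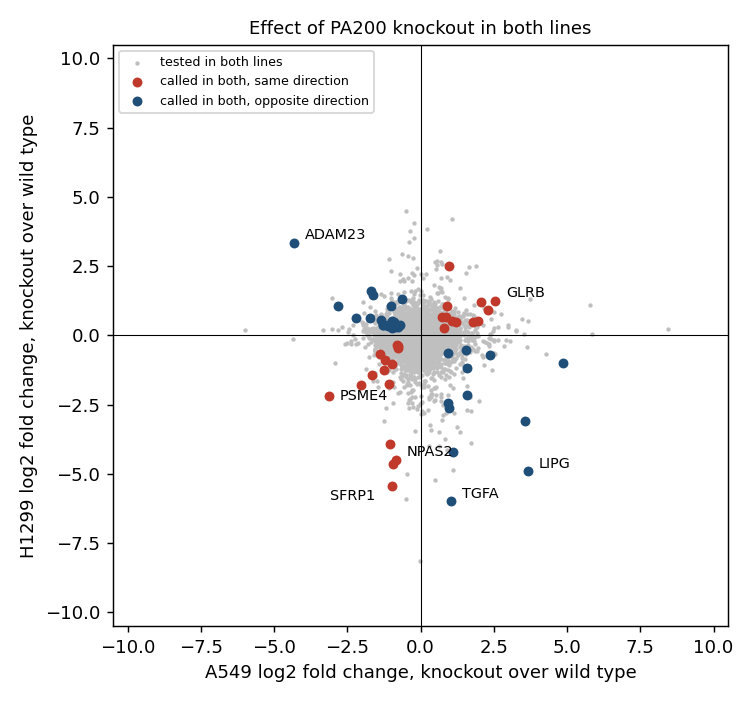
Log2 fold change of knockout over wild type in A549 (horizontal axis) and H1299 (vertical axis) for genes tested in both lines. Red points are the 27 genes called in both lines in the same direction and blue points the 32 called in opposite directions.

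In the fit over all 12 libraries, 788 of 22635 genes differed in their response between the lines, 445 with the higher log2 fold change in H1299 and 343 with the higher one in A549. ADAM23 fell in A549 and rose in H1299, a difference of 7.67 (SE 0.76, adjusted p = 0.000343). PRICKLE1, at -9.66 (SE 0.74, adjusted p = 4.17e-05), and TGFA, at -7.04 (SE 0.45, adjusted p = 1.01e-05), rose in A549 and fell in H1299 in the same fit. ADD2 differed by 4.96, with 4.48 in H1299 and -0.49 in A549, where it did not pass (adjusted p = 0.0958). The other named differences were F2RL2 (4.35), OLFM2 (3.88), AADACP1 (4.58), ABCG2, a drug efflux transporter (3.74), LIPG (-8.60), GRAMD2B (-5.90), the sulfotransferase CHST15 (-5.73) and TRHDE, whose A549 wild-type libraries had 0 counts, so that its rise in A549 was at least 9.65-fold. AADACP1, a pseudogene, rested on 1 wild-type count in H1299 against 23 in the knockout (ratio 23.2, counting interval 3.77 to 956). In H1299 ABCG2 had 4 wild-type counts in total against 33 in the knockout, and OLFM2 had 8 against 33. ABCG2 also lies on the long arm of chromosome 4, shifted in H1299. Groups with few counts in total were also H1299 knockout for PRICKLE1 (5) and CHST15 (6) and A549 wild type for LIPG (7) and GRAMD2B (7). Of the called genes with a chromosome arm 43.9% lay on chromosome 2 or on the H1299 arms shifted above, against 16.4% of tested genes. The count of 788 was 1359 without A549 wild-type replicate 3, 376 without A549 knockout replicate 3, 411, 367 and 406 without H1299 wild-type replicates 1, 2 and 3, and 385, 310 and 327 without H1299 knockout replicates 1, 2 and 3.

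The average of the 2 knockout effects differed from 0 for 975 genes, 425 higher and 550 lower. Of those with a chromosome arm 37% lay on chromosome 2 or on the shifted H1299 arms, against 16.4% of tested genes. PSME4 had an average of -2.66 (SE 0.11, adjusted p = 4.58e-08), NPAS2 of -2.67 (SE 0.19, adjusted p = 1.41e-05), SFRP1 of -3.20 and FIBCD1 of -2.16. GLRB averaged 1.91 (SE 0.29, adjusted p = 0.00662), TRPM6, a magnesium channel, 1.91 and GABRQ 2.03. TRPM6 missed the threshold in DESeq2 (adjusted p = 0.058). CCL28, a mucosal chemokine, had 0 counts in the A549 wild-type libraries and was at least 6.79-fold higher in A549 knockout. Of these genes only PSME4 passed in both lines in this fit. GLRB, GABRQ and CCL28 passed in A549 only, and NPAS2, SFRP1 and FIBCD1 in H1299 only. TRPM6 passed in neither (adjusted p = 0.158 in A549 and 0.142 in H1299). In H1299 GABRQ stood at 0.61 and CCL28 at 0.41, and GABRQ had 8 counts in total in A549 wild type. For ADD2 (1.99), GRAMD2B (1.94), TGFA (-2.47) and CHST15 (-2.36) the average joined estimates of opposite sign in the lines. The count was 621 and 2265 without A549 wild-type replicates 2 and 3, 493 and 436 without A549 knockout replicates 1 and 3, 581, 339 and 481 without H1299 wild-type replicates 1, 2 and 3, and 556, 350 and 306 without H1299 knockout replicates 1, 2 and 3.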

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

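The test by the share of signs and the centring within arms were chosen only after the results were seen, while the regrouping test was set before. Each result here was singled out because the knockout effect differed between the lines. The fit over 12 libraries called 788 genes for the difference (H1299 minus A549). The named genes with the larger log2 fold change in H1299 were ADAM23 (7.67), ADD2 (4.96), AADACP1 (4.58), F2RL2 (4.35), OLFM2 (3.88) and ABCG2 (3.74). Those with the larger one in A549 were PRICKLE1 (-9.66), LIPG (-8.60), TRHDE (-7.60), TGFA (-7.04), GRAMD2B (-5.90) and CHST15 (-5.73). The value for TRHDE is a fitted one and no measured size: it had 0 counts in A549 wild type, and its rise in A549 was at least 9.65-fold. AADACP1, ABCG2 and OLFM2 had 1, 4 and 8 counts in total in H1299 wild type, so their values are uncertain in size. PSME4 itself fell less in H1299, by 0.91, with 21.7% of the wild-type level left against 11.5% in A549. With libraries centred within arms PSME4 stood at -2.66 in A549 and -2.25 in H1299, so part of this difference went with the shift of chromosome 2 in A549. Among 60 regroupings of genotype within lines, drawn from 200 possible ones, 2 gave at least 788 genes, the real one included. The other gave 975 and relabels every library of a line, which swaps the difference and the average by construction.

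The log2 fold changes of the lines had little relation to each other. A technical explanation is that shifts of chromosome arms hide a shared response; after centring within arms the Spearman rho across genes was 0.096 against 0.07 before, so the centring did not uncover one. Another is that the A549 libraries were too variable to call shared genes. Of the genes called in H1299 53.3% had the same sign in A549, close to an even split. Variable A549 values would also move this share towards an even split, so it cannot decide and this explanation stays open. A response to PA200 loss that differs between the lines, or changes that came with deriving the edited cells in each line, also remain possible and were not tested. The labels do not say how many clones were used.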

How the results depend on the processing

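Centring within arms, removal of chromosome 2 or of shifted arms, thinning and the loess correction were chosen only after the results were seen; the other alternatives were planned. The fall of PSME4 kept its direction and call in every alternative, from -3.25 to -2.66 in A549 and from -2.26 to -2.16 in H1299.

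In A549 430 genes were called. The count was 1275 with no low-count filter, 1540 with DESeq2, 1772 in the 12-library fit, which shares its variance estimate with H1299, and 987 (355 higher, 632 lower) after the loess correction. It was 236 (146 higher, 90 lower) after centring within arms, 153 without chromosome 2, 176 without the shifted long arm of chromosome 2, 8 at an adjusted p under 0.01, a stricter threshold, and 10 to 1016 with 1 library left out. In H1299 1786 genes were called. The count was 3077 with no filter, 559 in the 12-library fit, 323 at an adjusted p under 0.01, 376 with a 2-fold threshold, 928 without the shifted arms and 471 to 1469 with 1 library left out. Of the 277 A549 calls lost without chromosome 2, 134 lay on it, and of the 858 H1299 calls lost without the shifted arms, 556 lay on them. Removal did not refit the data and only adjusted the same p-values again over the genes left. The other 143 calls in A549 and 302 in H1299 were therefore lost through that adjustment. They had passed only with the removed genes among those tested. For the other alternatives, except the stricter thresholds, the cause was not tested.

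The difference between lines had 788 genes, 1239 with no filter, 1707 with DESeq2 and 310 to 1359 with 1 library left out. The average had 975, 2152 with DESeq2 and 306 to 2265 with 1 library left out. The 27 genes called in both lines in the same direction became 8 with a 2-fold threshold, 107 with DESeq2, 13 after centring within arms and 1 to 64 with 1 library left out; the cause was not tested. CCNA2, RPL34 and RPL7 in H1299 changed sign after centring within arms, to -0.07, -0.06 and -0.03, none of them called; they lie on arms whose median shift that step removes.

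All 10 camera calls were lost with an estimated correlation, but that setting called no list in either line. Its lowest adjusted p was 0.617 in A549 and 0.634 in H1299. Extracellular matrix in A549, with an estimated correlation of 0.018 against the preset 0.01, went from a camera adjusted p of 0.0539 to 0.714. A loss in this setting therefore does not by itself show that correlation between members undid a call. The estimate was far above the preset for ribosomal proteins (0.88) and the respiratory chain (0.531) in A549 and for G2/M genes (0.381) in H1299. For these lists such correlation may have undone the call. In the other called lists it ran from 0.085 (NRF2 targets, A549) to 0.178 (double-strand break repair, H1299). Over all alternatives the adjusted p ran from 3.76e-09 to 0.617 for NRF2 targets, 1.61e-09 to 0.947 for ribosomal proteins, 0.000198 to 0.714 for alveolar and airway genes and 0.000656 to 0.947 for the respiratory chain in A549. In H1299 it ran from 0.00187 to 0.634 for TGF-beta targets, 0.00736 to 0.634 for immunoproteasome and MHC class I genes, 0.0017 to 0.736 for G2/M genes, 0.0105 to 0.634 for extracellular matrix, 0.00571 to 0.634 for double-strand break repair and 0.0017 to 0.634 for the respiratory chain. Calls were gained after centring within arms by extracellular matrix in A549 (0.0395) and by ribosomal proteins (0.0144) and other proteasome activators (0.0378) in H1299. With 1 library left out they were gained by extracellular matrix (0.0149 and 0.0246) and histones (0.0144) in A549 and by ATF4 (0.0233 and 0.0253) and NF-kappaB genes (0.0314) in H1299; the cause was not tested. Of the named called genes 4 of 52 in A549 and 38 of 95 in H1299 were called whichever library was left out.

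Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In A549 1 of 10, the real one, reached its count of 430, and the highest other gave 1. In H1299 1 of 10 reached 1786 and the highest other gave 0. For the average 1 of 60 regroupings reached 975, and the highest other gave 788. That other one relabels every library of a line, so its average is the real difference by construction. The highest of the rest gave 221. Depth differed with genotype in A549; thinned to 1 depth, it gave 358 calls.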

Other observations

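The test of a local effect around the edited site was chosen only after the result was seen, as were the correction for GC content and length and the thinning. In A549 the knockout libraries were lower along chromosome 2. A different copy number of chromosome 2 in the A549 groups is a hypothesis. The smaller gap between the lowest wild-type and the highest knockout library over both arms was 0.30 on the log2 scale, but any cause of the shift would separate the libraries, so this value does not favour copy number. A local effect at PSME4, confined to the short arm, would spare the long arm, whose median was -0.47. That value cannot decide on an effect of editing that reaches the whole chromosome, which was not tested. The median over chromosome 2 was -0.53 after the correction for GC content and length and -0.455 after thinning, so neither accounted for the shift. In H1299, where PSME4 also fell, the chromosome 2 median was 0.04 and 41% of its expressed genes were below 0. These values argue against a response of chromosome 2 to PA200 loss that both lines share. No DNA was measured here, and a response in A549 alone stays open.

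In H1299, 4 of the 4 shifted arms on chromosomes 1, 4 and 8 stayed separated after the correction for GC content and length. The arms were chosen by a rule that includes separation, so this value does not favour the same copy number hypothesis there. All 4 kept a shift beyond 0.15, from -0.307 on the long arm of chromosome 1 to 0.343 on the long arm of chromosome 4, so GC content and length did not account for them. Whether the arms differed before or after editing was not tested.

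A549 wild-type replicate 3 lay with the knockout libraries on other arms. On the short arm of chromosome 8 its deviation was -0.141, against 0.189 and 0.279 in wild-type replicates 1 and 2 and -0.085, -0.174 and -0.113 in the knockout libraries. On the long arm of chromosome 15 it was 0.119, against -0.235 and -0.216 in the other wild-type libraries and 0.110, 0.098 and 0.115 in the knockout libraries. These arms differed within a genotype.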
